A study of Mus musculus with 16 samples.

How the data were processed

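The series tested fragments of open chromatin from mouse embryonic stem cells for their ability to switch on a reporter gene. Per the labels, nucleosome-free DNA was released enzymatically from cross-linked nuclei and cloned in front of a minimal promoter driving green fluorescent protein (GFP) in a lentiviral plasmid. Such a fragment is called a nucleosome-free region (NFR) below. Stem cells were transduced with the pooled virus at a multiplicity of infection of 7, selected with 250 µg/ml hygromycin B for 5 days, and sorted for GFP. Fragments were then rescued by PCR, from the plasmid libraries with 16 cycles on 50 ng of DNA in 6 pooled reactions, and from genomic DNA of at least 1000000 sorted cells with 23 cycles on 100 ng in 10 pooled reactions.

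The 16 samples fall into 2 groups, 4 samples of the input plasmid library and 12 samples of GFP-selected cells. In each group the sample titles name 2 restriction digests, Rsa and Hae, with 2 replicates of each digest. Each GFP-selected replicate was measured as 3 technical replicates. The titles and the descriptions of the library samples name the enzymes in opposite ways, so no result below is tied to an enzyme.

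The deposited files are 2 lists of genomic intervals, 1 for each group, with chromosome, start and end and no read count or score. Per the submitters' processing notes, reads were mapped with BWA to the mm9 build, with no version stated. The way in which the authors called intervals, the minimum number of reads and the pooling of replicates are not given in the sources used here. The library list extends to 152.5 Mb on chromosome 7, beyond the last gene of that chromosome at 145.3 Mb in the GRCm38 gene table at hand, so that table was not used. Positions are printed as listed. The lists do not state whether starts count from 0 or 1, so a start may be off by 1 base. Length is end minus start.

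No list gives values per sample. The unit of every test was therefore the interval, p-values measure the spread among intervals and not between replicates, and read depth is unknown. Binomial intervals (exact, Clopper-Pearson, 95%) cover counting error of intervals only.

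The library list restarts its run of chromosomes several times. These runs divide it into 4 sections: short section 1 with 244 intervals, the first long section with 45165, short section 3 with 1206, and the second long section with 37625. The labels do not say what the sections are, and they are not groups of the study. The division was made after the lists were seen. The GFP-selected list likewise has 2 parts, of 4766 and 1598 intervals. Of the 1450 intervals in the 2 short sections, 1442 were identical to a GFP-selected interval. All results are therefore given within the long sections beside the values for the whole list.

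Identical library intervals were counted once, which left 82650 distinct intervals of 84240 listed. A library interval was called active when a GFP-selected interval overlapped at least 50% of its length and was itself overlapped over at least 50% of its length (bedtools 2.31.1), and inactive otherwise. A cell transduced at this multiplicity of infection can carry more than 1 fragment, so active means rescued from GFP-positive cells, and fragments that only shared a cell with a functional one can be included. Shares by chromosome were compared by two-sided Fisher's exact tests of each chromosome against all others. Median lengths were compared by two-sided permutation tests with 100000 resamples. Crowding was the number of other library intervals with a midpoint within 1 kb or 10 kb, with Fisher's exact test of 5 or more against 0. The activity of nearest neighbours was compared by odds ratios in 6 classes of gap, with one-sided p-values from 100 permutations of activity within chromosomes. Bins of 100 kb with at least 5 library intervals were tested by one-sided exact hypergeometric tests. Odds ratios have Woolf 95% intervals. Values stratified by section are Mantel-Haenszel odds ratios, stratified hypergeometric tests, or permutations within sections. Adjusted p-values are Benjamini-Hochberg values over the tests of a family, with a threshold of 0.05. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9.

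By a rule fixed before the data were examined, the text names every chromosome past an adjusted p of 0.05 and up to 10 bins past that threshold. The tests were fixed at the same time, together with other settings to try. Those were another rule for matching intervals, merged library intervals, autosomes only, intervals of 100 to 300 bp, another radius, other bin sizes and the mean in place of the median. Alternatives that use the sections, leave out overlapping intervals, compare mean lengths within them, count every listed line, or draw 1000 permutations were added after the lists were seen.

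The procedures were tested on simulated activity laid over the real library. In 20 simulations without any effect, 0 of 5950 bins and 0 of 22 chromosomes were called in each. With 40 bins, each of at least 12 library intervals, set to an active share of 50% against 6% elsewhere, 77% of them were called in 5 simulations, with 2 false calls in all. An odds ratio of 1.5 planted on chromosome 11 was called in all 20 simulations. Where only the sections differed in activity, the pooled crowding odds ratio had a median of 2.03 and the stratified one a median of 1.01. In all of these simulations activity was drawn independently for each interval. They therefore do not cover overlapping library intervals made active by the same GFP-selected interval, which occur in the data.

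Comparisons that need the mm9 sequence or annotation were fixed but not run. They were position relative to genes, base composition, enzyme sites at interval ends, sequence motifs and nearby genes. Genes are not named for the same reason.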

Results

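The data cover 16 sequenced samples from mouse embryonic stem cells of the E14 line, a pluripotent line grown in culture. In 4 samples, NFRs were sequenced from the plasmid library before it entered cells. In 12 samples, NFRs were rescued from sorted cells that expressed GFP from the integrated reporter. The library was listed as 84240 intervals, 82650 of them distinct, with lengths from 98 to 1650 bp and a median of 160 bp (quartiles 136 and 187 bp). Together the distinct library intervals summed to 14.0 Mb. The GFP-selected list held 6364 intervals of 100 to 2526 bp, with a median of 165 bp (quartiles 132 and 220 bp), and summed to 1.18 Mb. There were no values per replicate, so no error between replicates can be given for any result.

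The first question was whether the NFRs rescued from GFP-positive cells were fragments of the library that had been put in. Most of them were. Of the 6364 GFP-selected intervals, 5957 (93.6%, 95% interval 93.0 to 94.2%) matched a library interval at 50% reciprocal overlap. The same intervals placed at random on their chromosomes matched at a median of 0.471%, and at most 0.660% in 100 placements. All 6364 overlapped a library interval by at least 1 bp, and 4838 (76.0%) had the identical start and end. The 407 GFP-selected intervals without a reciprocal match were longer, with a median of 265 bp against 164 bp for those matched. Part of the recovery came from the short sections of the library list, of whose 1450 intervals 1442 were identical to a GFP-selected interval. Matched against the long sections alone, recovery was 72.4% (95% interval 71.3 to 73.5%) at 50% reciprocal overlap and 80.0% with any overlap, which leaves 1272 GFP-selected intervals without any overlap there.

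The sections of the library contributed unequally to this recovery. The second long section matched 68.3% of the GFP-selected intervals and the first long section 12.3%, although the first listed more intervals. Intervals identical to a GFP-selected interval numbered 2940 among those listed only in the second long section and 262 among those listed only in the first.

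The second question was which fraction of the library was rescued from GFP-positive cells. Of the 82650 distinct library NFRs, 6199 were active, a share of 7.50% (95% interval 7.32 to 7.68%; jackknife SE over 22 chromosomes 0.194%). The share depended strongly on the section. It was 1.73% in the first long section (783 of 45165, 95% interval 1.62 to 1.86%) and 11.5% in the second (4345 of 37625, 11.2 to 11.9%). Intervals listed only in the second long section were active 10.2 times as often as those listed only in the first, with shares of 11.2% and 1.10% and an odds ratio of 11.3 (95% interval 10.3 to 12.5). NFRs listed identically in both long sections had a higher share still, 19.9% (303 of 1521), with an odds ratio of 1.97 against intervals of the second section only (95% interval 1.73 to 2.25, Fisher's exact p = 5.43e-22). Of the 1381 intervals found only in the short sections, 1374 (99.5%) were active, and nearly all intervals of these sections were identical to a GFP-selected one. Without those intervals the share over both long sections was 5.94%.

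The third comparison asked whether active NFRs differed in length from inactive ones. Over the whole list, active NFRs were slightly longer, with a median of 164 bp against 160 bp, a difference of 4 bp (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Within the long sections the medians went the other way. Active NFRs were 155 bp against 159 bp in the first long section (permutation p = 0.00012) and 159 bp against 162 bp in the second (permutation p = 0.0168). Averaged over sections, the difference was -2.98 bp (permutation within sections, p = 0.00068). Without the short sections, whose active intervals had a median of 209 bp, the difference of medians was -2 bp (permutation p = 0.0432, adjusted p = 0.054). Mean lengths gave another picture. Active NFRs were on average 13.6 bp longer in the whole list and 3.51 bp longer without the short sections (172 against 169 bp, permutation p = 3e-05). Within the long sections the means did not differ past the threshold, at 1.69 bp in the first (permutation p = 0.319) and -0.78 bp in the second (permutation p = 0.433).

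The relation between length and activity was not monotonic. In the whole list the active share was 8.17% in the shortest quintile (98 to 129 bp), fell to 4.88% at 154 to 169 bp and was 11.9% in the longest quintile (197 bp and more). Without the intervals that stood only in the short sections these shares were 7.30%, 4.06% and 7.60%, so much of the height of the longest class came from the short sections. The first long section had the same shape at a lower level, with 2.51%, 1.10% and 2.42% in these classes, and the exact 95% intervals of the middle class did not overlap those of the outer ones. In the second long section the shares ranged only from 10.2% to 12.3%. The share at 154 to 169 bp, the most common lengths of the first section (11184 intervals), was close to the 1.24% at 170 to 196 bp, and their 95% intervals overlapped.

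**Figure D1:**
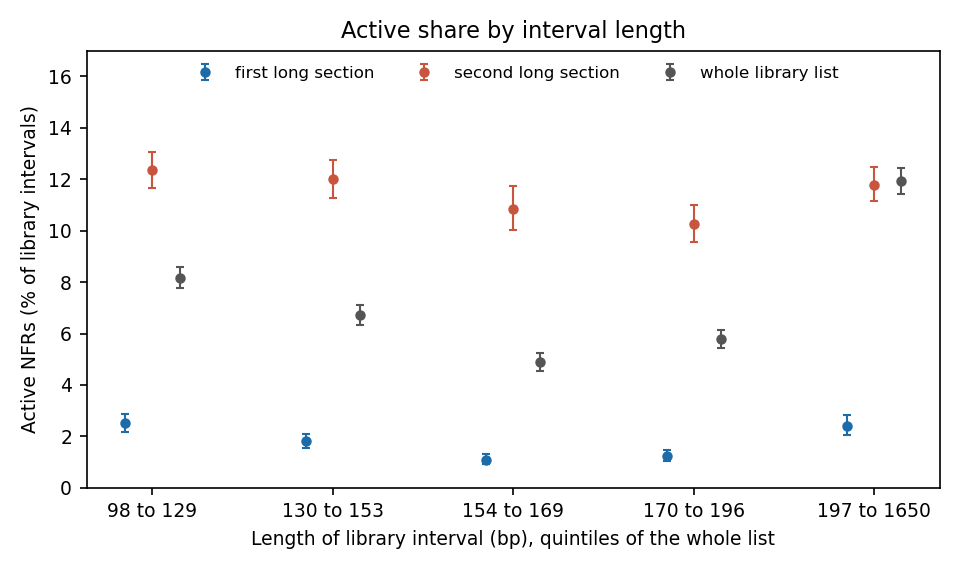
Share of library NFRs that were active (y axis, percent) against interval length (x axis, bp, quintiles of the whole list); points are shares and bars exact 95% binomial intervals, for the first long section, the second long section and the whole list. The whole list, which includes the short sections, runs from 4.88% at 154 to 169 bp to 11.9% in the longest class, while the second long section stays between 10.2% and 12.3%.

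The fourth comparison asked whether active NFRs were spread over the chromosomes as the library was. In the whole list, 7 of 22 chromosomes differed from the rest. Chromosomes 7 (8.58% active, odds ratio 1.17, adjusted p = 0.0104), 11 (8.83%, odds ratio 1.21, adjusted p = 0.00104) and the mitochondrial chromosome M (42.9%, odds ratio 9.26, adjusted p = 0.00021) had more active NFRs. Chromosomes 1 (6.36%, odds ratio 0.828), 14 (6.05%, 0.788), 16 (6.31%, 0.825) and 18 (6.29%, 0.823) had fewer. The X chromosome had 6.32% (adjusted p = 0.0856), and 0 of 37 library intervals on Y were active, which allows a share of up to 9.49% (exact 95% interval).

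The differences among nuclear chromosomes were small, and none passed the threshold in both long sections. In the first long section, chromosomes 7 (2.61%, odds ratio 1.57) and 11 (2.71%, odds ratio 1.64) stood above the rest. Of the 783 active intervals of that section, 303 were also listed in the second. Another 290 overlapped an interval listed only in other sections. Whether chromosomes 7 and 11 stand out without these intervals was not tested. In the second long section, the odds ratios of these chromosomes were 1.01 and 0.993, and no nuclear chromosome passed the threshold. Chromosomes 1, 14, 16 and 18 had odds ratios of 0.702, 0.578, 0.665 and 0.771 in the first long section. In the second they had 0.963, 0.925, 0.825 and 0.975. All of these lay below 1, and none passed the threshold. Stratified by section, chromosome M alone passed it. With identical start and end required for a match, chromosome 11 alone did (odds ratio 1.2, adjusted p = 0.0256). With the short sections left out as well, its adjusted p was 0.0789, and chromosome 16 alone passed (odds ratio 0.707, adjusted p = 0.0349).

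**Figure D2:**
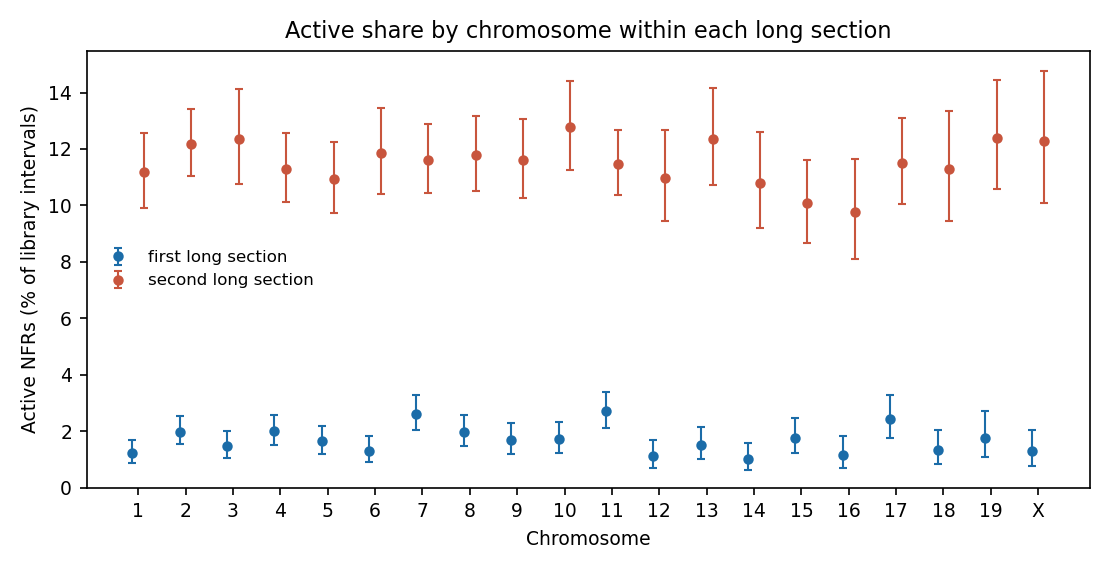
Share of library NFRs that were active (y axis, percent) on each autosome and on X (x axis), with exact 95% binomial intervals, for the first and the second long section; M and Y are not drawn. Every chromosome lies far higher in the second long section, where chromosome 11 has an odds ratio of 0.993 against the others.

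Mitochondrial DNA, which is not packaged in nucleosomes, gave the highest active share of any chromosome. Of its 21 library intervals, 9 were active (42.9%, 95% interval 21.8 to 66.0%), and the odds ratio stratified by section was 24.9 (95% interval 7.90 to 78.6; exact one-sided stratified hypergeometric p = 3.99e-08). Active intervals made up 3 of 13 in the first long section and 6 of 8 in the second. The 7 GFP-selected mitochondrial intervals lay at positions 1612 to 2000, 2656 to 2833, 3704 to 4447, 12358 to 12673, 12736 to 13000, 13010 to 13495 and 14720 to 15158 of chromosome M (mm9). Those at 2656 to 2833 and 3704 to 4447 each matched an interval in both long sections. The stratified odds ratio and p-value treat such matches as independent. With overlapping library intervals merged, 6 of 15 regions were active (odds ratio 8.45, 95% interval 3.01 to 23.7, Fisher's exact p = 0.00043). Mitochondrial library intervals were long, with a median of 362 bp against 160 bp elsewhere. They were also dense, at 1319 per Mb of covered span against 47.7 on chromosome 11, the densest nuclear chromosome. The call depended on the matching rule: with identical start and end required, 3 of 21 were active (odds ratio 2.68, adjusted p = 0.283). With intervals of 100 to 300 bp only, the odds ratio was 6.38 (95% interval 1.59 to 25.5) and the adjusted p 0.0637.

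**Figure D3:**
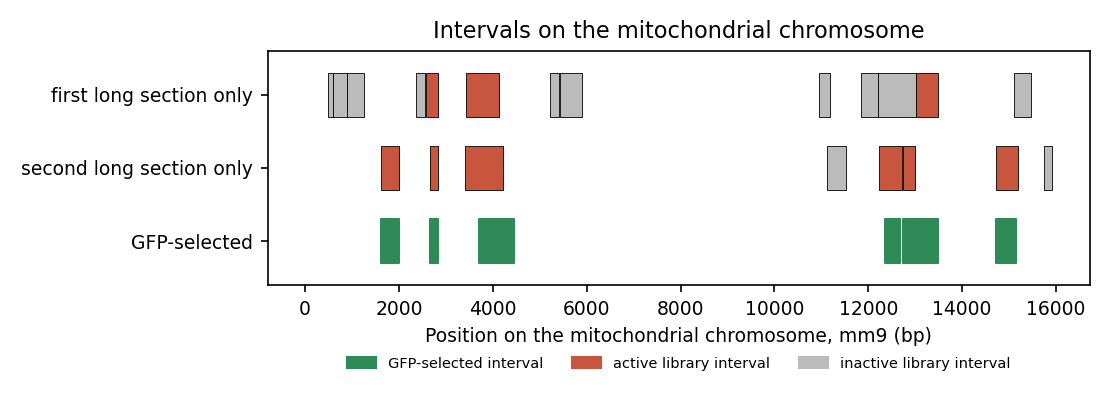
Map of chromosome M (x axis, position in bp, mm9) with the 7 GFP-selected intervals and the 21 library intervals of the first and the second long section. Active library intervals are coloured red and inactive ones grey; 6 of 8 are active in the second long section and 3 of 13 in the first, and the GFP-selected intervals at 12736 to 13000 and 13010 to 13495 appear joined at this scale.

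The fifth comparison asked whether NFRs from densely captured regions were active more often. In the whole list they were. The active share was 4.82% for NFRs with 0 other library intervals within 10 kb, 7.38% with 1, 10.3% with 2 to 4 and 13.0% with 5 or more. The odds ratio of 5 or more against 0 was 2.96 (95% interval 2.68 to 3.26, Fisher's exact p = 3.33e-90). Within 1 kb the share went from 5.83% with 0 others to 24.5% with 5 or more, the latter over only 49 intervals (odds ratio 5.24). In the first long section alone, 0 of 9 intervals with 5 or more others within 1 kb were active, against 1.65% of those with 0 others. The odds ratio of 3.13 there (95% interval 0.182 to 53.8, Fisher's exact p = 1) shows no rise. It came only from a constant added to each count because of that 0. In the second long section the odds ratio within 1 kb was 2.69 (95% interval 0.543 to 13.3, Fisher's exact p = 0.218).

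The rise differed between the sections. With neighbours counted within the section, the share in the second long section went from 11.1% to 12.5% (odds ratio 1.15, 95% interval 0.964 to 1.36, Fisher's exact p = 0.127). In the first long section the share went from 1.50% with 0 neighbours through 1.86% and 2.76% to 10.9% with 5 or more (11 of 101, odds ratio 8.02, 95% interval 4.26 to 15.1, Fisher's exact p = 4.52e-07). Crowded intervals lie near one another by definition, so these 101 need not come from as many separate places. Fisher's test and the 95% interval treat them as independent and can overstate the certainty, as in every crowding comparison here. Stratified by section, with neighbours counted over the whole list, the odds ratio was 1.55 (95% interval 1.39 to 1.73), and 1.53 with the short sections left out. By that count, none of the 2658 intervals that overlapped or touched another library interval could have 0 others, while 166 of the 581 with 5 or more were active. Without these 2658 intervals the odds ratio was 2.41 pooled (95% interval 2.16 to 2.69) and 1.11 stratified by section (95% interval 0.978 to 1.26). It was 1.07 for intervals of the second section only (95% interval 0.931 to 1.22) and 3.12 for those of the first only (95% interval 1.73 to 5.64, 13 of 1165 against 76 of 21107 active). Crowded places held more of the second section: intervals listed only there made up 33.0% of NFRs with 0 others within 10 kb and 64.7% of those with 5 or more.

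**Figure D4:**
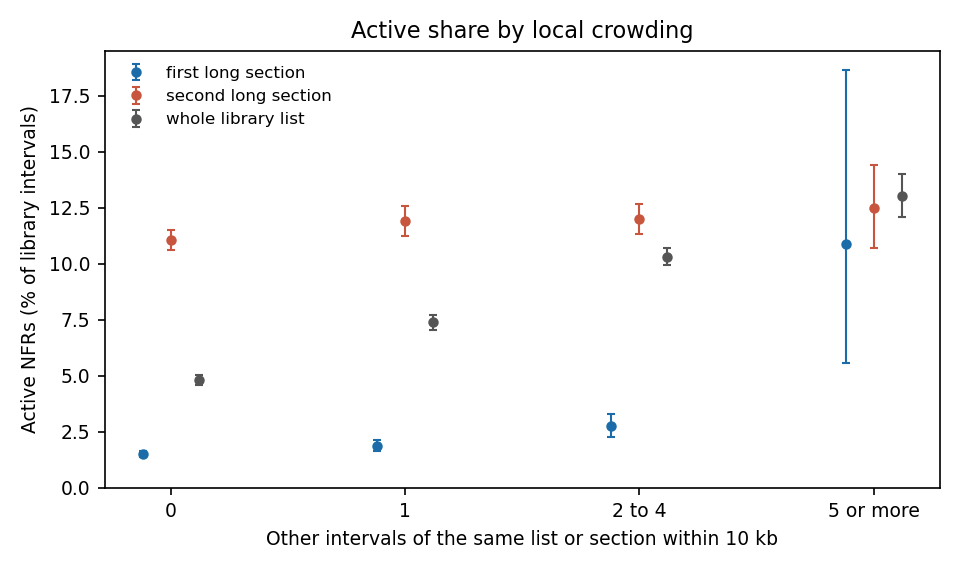
Share of library NFRs that were active (y axis, percent) by the number of other intervals of the same list or section within 10 kb (x axis), with exact 95% binomial intervals. The whole list rises from 4.82% to 13.0%, the second long section goes from 11.1% to 12.5%, and the class of 5 or more in the first long section (10.9%) rests on 101 intervals.

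The sixth comparison used neighbouring fragments as a repeat measurement of a locus. Among NFRs whose nearest neighbour overlapped or touched them, the neighbour was active for 70.1% of active NFRs and for 11.3% of inactive ones (odds ratio 18.5, 95% interval 14.9 to 22.9). Intervals nearest to each other were counted from both sides: the 2658 intervals of this class held 1369 overlapping nearest pairs. The 95% interval treats both counts as independent and is too narrow, in every class of gap, while the permutations keep the pairing. The permutation p was 0.0099, the smallest that 100 permutations can give, and 0.0594 after adjustment over 6 classes of gap. With 1000 permutations it was 0.000999, again the smallest possible, and 0.00599 after adjustment. This similarity follows largely from the matching rule, because in 242 of the 247 overlapping pairs with both members active a single GFP-selected interval matched both. Without overlap the relation was weaker. At gaps of 1 to 500 bp the neighbour was active for 18.1% of active and 13.1% of inactive NFRs (odds ratio 1.47, permutation p = 0.0396, adjusted p = 0.119), and with permutation within sections p was 0.317. With any overlap counted as a match, the odds ratio at these gaps was 2.30 (permutation p = 0.0099, adjusted p = 0.0297), and with autosomes only it was 1.45 with the same p-values. Where any overlap counts, 1 GFP-selected interval reaching across a gap makes both neighbours active, so the 2.30 can follow from that rule. How often this occurred was not counted. Without the short sections the odds ratio at these gaps was 1.24 (permutation p = 0.198, adjusted p = 0.25). With 1000 permutations over the whole list the adjusted permutation p at these gaps was 0.0719. At gaps over 2000 and up to 10000 bp the odds ratio was 1.03 in the whole list. In the first long section the odds ratios were 3.33 at 1 to 500 bp (permutation p = 0.208), 3.42 over 500 and up to 2000 bp (permutation p = 0.139) and 3.17 over 2000 and up to 10000 bp (12 of 212 active NFRs with an active neighbour, permutation p = 0.0099, adjusted p = 0.0495). In the second long section they were 1.03, 1.11 and 1.09, none past the threshold.

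The last comparison looked for loci with more active NFRs than their number of library intervals predicts. Of 5950 bins of 100 kb, 2 passed the threshold, against a median of 0 and at most 1 in 100 permutations of activity, and 302 had an unadjusted p under 0.05. The first lies on chromosome 9 from 106300001 to 106400000 (mm9), where 10 of 24 library NFRs were active against 1.80 predicted (hypergeometric adjusted p = 0.0244). The other bin holds chromosome M, with 9 active against 1.58 predicted (adjusted p = 0.0284). In the chromosome 9 bin, 2 of the 10 active NFRs stood only in the short sections. Over the long sections alone it had 8 active of 22 against 1.31 predicted (adjusted p = 0.0669), and with the prediction also stratified by section 2.05 were predicted (adjusted p = 0.394). In the same stratified test the mitochondrial bin had 1.04 predicted and an adjusted p of 0.000231. Tested alone, the first long section gave 0 of 1568 bins (28 at an unadjusted p under 0.05) and the second 0 of 2245 (51 at an unadjusted p under 0.05). With identical start and end required, or with overlapping library intervals merged, 0 bins passed in the whole list. After merging, the mitochondrial bin had an adjusted p of 0.419 (hypergeometric test). In 3136 of the 5950 bins no library NFR was active.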

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

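The tests of differences between the long sections below, the tests on the matching rule, the test of the second section's share within length quintiles, the removal of overlapping intervals and the stratification by section were chosen only after the result was seen. Among 8 relations compared between the first and the second long section of the library, 3 differed past an adjusted p of 0.05 (Wald test of the ratio of odds ratios). That test treats the sections as independent, although they share 1521 intervals, 303 of them active. The sections are runs in the list and not groups of the study. The crowding odds ratio was 6.99 times as large in the first section as in the second (95% interval 3.63 to 13.5, adjusted p = 5.09e-08), with neighbours counted within each section. Crowded intervals can come from the same places, and the test treats them as independent. Between first-only and second-only intervals, with neighbours counted over the whole list, the ratio was 13.2 (9.36 to 18.5). With overlapping intervals left out as well it was 2.93 (1.60 to 5.38). The odds ratio of chromosome 7 was 1.56 times as large in the first section (1.18 to 2.06, adjusted p = 0.00476), and that of chromosome 11 was 1.65 times as large (1.26 to 2.16, adjusted p = 0.00114). Neither was repeated without the first-section intervals that overlapped an interval of another section.

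Intervals of the second long section were active far more often than those of the first. With any overlap counted as a match, the share of second-only intervals was still 8.99 times that of first-only intervals, which argues against the matching rule as its cause. Within 100 kb bins the odds ratio was 8.17 (95% interval 7.32 to 9.12), which argues against the region of the genome at that scale. Location inside those bins, such as position relative to genes, was not tested. Within length quintiles the odds ratio was 10.7 (9.71 to 11.8), against length. A difference in how deeply the material behind each section was sequenced or selected stays open, since the lists hold no depth. The design names 2 digests, but the labels do not tie them to the sections, so no biological explanation was tested.

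The rise of activity with crowding was partly a mixture of sections. Stratified by section the odds ratio fell from 2.96 to 1.55 (95% interval 1.39 to 1.73), so the mixture is a candidate explanation of part of the rise. The rest does not show an effect of crowding by itself, because an interval that overlaps another can never have 0 neighbours and overlapping intervals were active often, partly through the matching rule. Without overlapping intervals the stratified odds ratio was 1.11 (0.978 to 1.26), although it stayed at 3.12 (1.73 to 5.64) for first-only intervals. Whether anything beyond mixture and overlap is needed stays open. Length did not remove the pooled rise of the whole list, with an odds ratio of 2.67 within length quintiles (2.42 to 2.95). Sections were mixed and overlapping intervals kept there, so this value does not bear on what is left beyond mixture and overlap. In the first long section, intervals overlapped by an interval listed only in other sections were active in 23.0% of cases, against 1.12% of the others. The other sections here include the short ones, nearly all identical to GFP-selected intervals. The 1521 intervals listed identically in both long sections counted among the others, and 303 of them were active. Of first-only intervals without such an overlap, 0.448% were active. Without the overlapped intervals the odds ratio in that section was 5.70 (2.07 to 15.7), which rests on 4 active intervals of 73 in the most crowded class. This value keeps the 1521 shared intervals, so it does not remove every coincidence with the second section.

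The high active share of mitochondrial intervals was kept within length classes (odds ratio 6.28, 95% interval 2.59 to 15.2) and after merging overlapping intervals (8.45, 3.01 to 23.7), which argues against length and repeated counting as its whole cause. With identical start and end required, the odds ratio was 2.68 (0.79 to 9.11), so a looser match to long intervals may account for part of it. That interval reaches almost to the odds ratio of 9.26 under the main rule, and only 3 intervals were active. The presence of mitochondrial DNA of the sorted cells in the rescue PCR was not tested. The abundance of mitochondrial fragments in the library was not tested either, since the lists hold no depth. No biological explanation was tested.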

How the results depend on the processing

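The alternatives that use the sections (mean lengths within them included), leave out overlapping intervals, count every listed line or draw 1000 permutations were chosen after seeing the data; the others were fixed before. No paired analysis was possible because the lists pool all replicates, and leaving out a replicate or splitting the samples was not possible for the same reason. Comparisons that need mm9 sequence or annotation were not run. Merged intervals, like each long section alone, give no value for overlapping neighbours. Of 86 values of the main results under an alternative, 35 kept their direction and side of the threshold or stayed close to the main value.

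Recovery of GFP-selected intervals (93.6%) was 76.0% with identical start and end, 100% with any overlap, 72.4% without the short-section intervals, 54.4% with both identical ends and no short sections, 12.3% in the first long section and 68.3% in the second. The active share (7.50%) was 5.85% with identical ends, 8.38% with any overlap, 7.32% after merging, 7.80% with every listed line, 5.94% without short sections, 4.26% with identical ends and no short sections, and 1.73% and 11.5% in the long sections. The length difference (4 bp) was 8 bp after merging. It reversed to -2 bp without short sections, -7 bp with identical ends as well, and -4 bp and -3 bp in the first and second long section. Stratified by section it was -2.98 bp, and -3.05 bp when stratified without short sections. By the mean it was 13.6 bp, 3.51 bp without short sections, 1.69 bp in the first long section (no longer past the threshold) and -0.78 bp in the second. The 7 called chromosomes became 10 with any overlap, 6 each after merging, with autosomes only (of 19) and with every listed line, 5 without short sections, 1 with identical ends (chromosome 11), 1 with identical ends and no short sections (chromosome 16), 4 at 100 to 300 bp, 3 in the first long section, 1 in the second and 1 when stratified (with or without short sections). Chromosome 11 turned to an odds ratio of 0.993 in the second long section. The crowding odds ratio (2.96) lost the threshold at 1.15 in the second long section and, without overlapping intervals, at 1.07 for second-only intervals and 1.11 when stratified. Elsewhere it stayed past it, from 1.25 (second-only intervals) to 16.4 (first-only intervals). Both of these count neighbours over the whole list, where overlapping intervals cannot fall in the class of 0; without them the first-only value was 3.12. The odds ratio of overlapping neighbours (18.5, adjusted p = 0.0594) passed the threshold with any overlap (4420), autosomes only (18.8) and 1000 permutations (18.5). Without short sections, at 100 to 300 bp and with every listed line it was 38.5, 30.6 and 112, with the adjusted permutation p still 0.0594. With any overlap and with autosomes only, the unadjusted p was the smallest of 100 permutations as before, and the adjusted p fell only because the class of 1 to 500 bp also reached it, so these crossings say nothing about overlapping neighbours. It reversed to 0.0108 with identical ends and to 0.0243 without short sections as well, since 1 GFP-selected interval can then match only 1 library interval. The 2 called bins became 6 with any overlap, 1 each with autosomes only, 50 kb bins, 500 kb bins, without short sections and when stratified (with or without short sections), and 0 with identical ends (with or without short sections), merging, 100 to 300 bp, no minimum, or either long section alone. Except where stated, the cause was not tested.

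Of 173 further values for single chromosomes, bins and gap classes, 106 kept their direction and side of the threshold (adjusted p of 0.05). Another 59 kept the direction but lost the threshold, 3 passed it only under the alternative and 5 reversed. Of the 106, 58 were for gap classes, which had not passed the threshold in the main result and so could not lose it. Called chromosomes kept the threshold in 40 values and lost it in 42, and called bins kept it in 8 and lost it in 17. The reversals beside chromosome 11 were odds ratios of neighbours that passed no threshold before or after: 0.98 after merging (10 to 50 kb), 0.984 with every line counted (2 to 10 kb), 0.563 in the first long section (over 50 kb) and 0.936 with identical ends and no short sections (0.5 to 2 kb). Read depth is unknown, so a library interval that was active but rarely sequenced counts as inactive.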

Other observations

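The test of the spacing of intervals, the overlap of first-only by second-only intervals and the comparison with identical GFP-selected intervals were chosen only after the result was seen; the other tests on shared intervals and on unmatched GFP-selected intervals were written before their results were seen.

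Among the nuclear chromosomes, open chromatin was captured most densely on chromosome 11, with 47.7 library intervals and 4.33 GFP-selected intervals per Mb of its covered span. The X chromosome was captured far more sparsely, with 13.0 library and 0.828 GFP-selected intervals per Mb. The share of long-section intervals that came from the second section was 53.6% on chromosome 11 and 36.4% on X. The most crowded bin of 100 kb, on chromosome 11 from 3000001 to 3100000, held 35 library NFRs, of which 5 were active against 2.63 predicted. The median gap between neighbouring GFP-selected intervals was 135 kb, and 270 of 6343 neighbouring pairs lay within 1 kb of each other.

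Intervals that both long sections covered at partly different ends were also active often. First-only intervals overlapped by a second-only interval were active in 267 of 1223 cases (21.8%), against 213 of 42421 (0.502%) of the other first-only intervals. Second-only intervals overlapped by a first-only interval were active in 24.5% of cases (299 of 1222), against 10.7% (3743 of 34882) of the others. These shares partly follow from the matching rule, by which 1 GFP-selected interval can make both members of an overlapping pair active.

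Many intervals followed the one before at a gap of exactly 10 bp. This held for 632 of 43644 first-only intervals followed by a first-only interval, and for 1142 of 36104 second-only intervals followed by a second-only one. The next most common gap up to 50 bp, apart from 9 and 11 bp, was 3 bp with 21 and 18 cases. Across sections the 10 bp gap occurred in 20 and 15 cases. A hypothesis is that each long section comes from its own set of cleavage sites, as from 1 restriction enzyme each. The rate across sections was 0.0197 of the rate within sections. These are the counts from which the hypothesis arose, so they do not test it, and it stays open.

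Another hypothesis was that intervals listed in both long sections were carried over from the second section's sites into the first. If so, they would touch second-only intervals at a 10 bp gap over 3 times as often as first-only ones, each relative to that section's own rate. The ratio was 1.83, under the 3 that the hypothesis predicted. It rests on 74 contacts with second-only and 19 with first-only intervals, and no interval was computed for it. The test therefore did not bear the hypothesis out but cannot exclude carry-over. A further hypothesis was that GFP-selected intervals identical to no library interval (1526) may be made by the second section's sites. They shared exactly 1 end with a second-only interval in 817 cases and with a first-only interval in 77, a ratio of 10.6 (95% interval 8.39 to 13.6). Identical GFP-selected intervals already favoured second-only over first-only intervals by 11.2, so this ratio does not decide the question. The 817 are 53.5% of these 1526 intervals.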
